A study of Homo sapiens with 22 samples.

How the data were processed

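RNA was sequenced from 22 H2110 xenograft tumours, 6 on Vehicle and 4 on each of 4 drugs, from strand-specific libraries of total RNA. The deposited table holds raw read counts per gene for 58735 genes, whole numbers in 1 column per tumour. Per the submitters' processing notes, the tools used were fastp, HISAT2 (2.0.5), featureCounts (1.5.0-p3), DESeq2 (1.20.0) and edgeR (3.22.5) with the human genome hg38. The host species, the strand setting of the counting, the treatment of reads that map to several places, the annotation release and any removal of host reads are not given in the sources used here. Gene symbols and positions came from the table itself, and all 58735 genes lay at the same position in GENCODE 29, which gave the GC content of 58676 of them.

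Counts were analysed in R (4.3.3). Genes were kept by the edgeR (4.0.16) filter on low counts with its minimum of 10 and the 5 groups, which left 17652 genes with 99.718% of all counts. Libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted once to all 22 tumours with 1 mean per group. Each drug was compared with Vehicle and each pair of drugs directly, 10 comparisons in all, by 2-sided F-tests with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The common dispersion was 0.1357, a biological coefficient of variation of 0.3684. CPM used TMM library sizes, and log2 CPM a prior count of 2. The MAPK output score was compared by exact permutation of the tumours. Of 43 gene lists with 658 entries, 7 of them matched by an older symbol, 39 were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison. Correlations of log2 fold changes were set beside groups simulated without change against the same Vehicle tumours. Groups, comparisons, lists, tests and the rule for naming genes were fixed before the data were examined.

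Genes were named by a rule. For each drug against Vehicle it took the 6 largest rises and 6 largest falls among protein-coding genes past the threshold, with all treated tumours on one side of all Vehicle tumours and a mean log2 CPM of at least 2. For each pair of drugs it took 3 each way, and for each list described up to 4 members with the smallest adjusted p. It always took the 10 MAPK output genes, NRAS, HRAS, RIT1, PTPN11, MAP2K1, MAP2K2 and PPIA. Some genes that the rule takes are not reported here.

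The total count was 11160546 to 17265754 under Vehicle, 10353740 to 15005429 under RMC-7977, 11951272 to 15888488 under RMC-4550, 7761987 to 13133140 under trametinib and 12655067 to 15428394 under cobimetinib. The labels name no molecular identifiers, so the counting error of these totals is a lower bound on the error. The pipeline was tested on simulated data with the group sizes, depths and spread of these libraries and about 200 changed genes per drug. In 17449 genes for RMC-7977 against Vehicle, 0%, 19.7% and 63.64% of changes of 1.5-, 2- and 4-fold were found. In 17427 genes for RMC-4550 they were 0%, 27.27% and 77.27%, in 17400 for trametinib 3.03%, 32.84% and 71.21%, and in 17443 for cobimetinib 0%, 16.42% and 78.79%. For the 6 pairs of drugs they were 1.493% to 4.545%, 15.15% to 23.88% and 63.64% to 72.73%. Of 55 to 73 calls per comparison 0 to 3 were false and none had the wrong direction. Regrouped real tumours gave up to 1729 calls, so these rates may not hold for them.

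Alternatives were DESeq2 (1.42.0), RLE or library-size scaling, no filter or a mean CPM of at least 1, only the 2 groups compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a test against a log2 fold change of 0.5, and leaving out each tumour in turn. The score was also computed with a prior count of 0.5 and with fewer genes, and the lists with ranks or an estimated correlation. Chosen after seeing the data were leaving out libraries that stood apart, a correction for GC content, library weights (limma), and each set of 3 Vehicle tumours alone. The deviations from the group means of tumours with the same replicate number correlated over 0.1 in all 3 pairs of Vehicle with RMC-4550 (0.1704 to 0.7109) and with trametinib (0.1362 to 0.2021). The labels do not say what the number stands for, and no other 2 groups had all pairs over 0.1 (0.08125 to 0.3756 in RMC-7977 with cobimetinib). No tumour was left out of the main results. Sequencing reads were not used here.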

Results

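Gene expression was measured in 22 xenograft tumours of H2110, a human lung adenocarcinoma cell line, after oral dosing for 3 days of tumours that had reached about 300 mm³. The tumours fell into 5 groups, 6 on Vehicle and 4 on each drug. RMC-7977 (10 mg/kg) inhibits active RAS proteins, and RMC-4550 (30 mg/kg) inhibits the phosphatase SHP2 that PTPN11 encodes. Trametinib (0.3 mg/kg) and cobimetinib (3 mg/kg) both inhibit the kinases MEK1 and MEK2. The study asked, by its title, about RIT1, a RAS-related GTPase, as a drug target in this cancer. The 4 compounds act at successive steps of the pathway from SHP2 through RAS to MEK and ERK. Doses differ between compounds, so differences between drugs hold at these doses. Replicates were separate tumours by their labels, but nothing says that they came from separate animals. The p-values therefore measure the spread between these samples, which may be technical. Of all genes 17652 had enough counts to be tested.

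Some libraries stood apart from the rest of their group. In Trametinib replicate 4, 1.99% of the detected genes had only 1 or 2 counts and the most frequent count of a detected gene was 12. In RMC-7977 replicate 3 these values were 5.02% and 4, against 13.4% to 22.9% and 1 in the other 20 libraries. Ribosomal protein genes took 25.0% of the counts of Trametinib replicate 4 against at most 9.24% elsewhere, and mitochondrially encoded genes took 1.94% against at least 4.80%. The median correlation with the other tumours was 0.751 for this library, 0.933 for Vehicle replicate 1 and 0.936 for RMC-4550 replicate 1, and 0.944 to 0.977 for the others. The rank correlation of a library's deviation from the gene means with GC content was −0.624 in Vehicle replicate 1, −0.671 in RMC-4550 replicate 1 and −0.636 in RMC-7977 replicate 3. It was −0.658 to −0.149 under trametinib but 0.342 to 0.547 in the rest of Vehicle, so GC and drug were partly confounded. Gene counts are also given without Trametinib replicate 4 and without the 2 libraries with few low counts (it and RMC-7977 replicate 3). They are given too without the 4 libraries apart (these 2, Vehicle replicate 1 and RMC-4550 replicate 1), all settings chosen after seeing the data.

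The transcriptional output of the MAPK pathway was lower under all 4 drugs than under Vehicle. The score, the mean log2 CPM of the 9 tested genes of a fixed set of 10 ERK-responsive genes (EPHA4 had too few counts to be tested), was 4.81 ± 0.37 (SD, 6 tumours) under Vehicle. It was 2.67 ± 0.27 under RMC-7977, 3.31 ± 0.41 under RMC-4550, 3.23 ± 0.77 under trametinib and 4.18 ± 0.21 under cobimetinib (SD, 4 tumours each). The differences from Vehicle were −2.14 (RMC-7977), −1.50 (RMC-4550) and −1.58 (trametinib), with all 4 treated tumours below all 6 Vehicle tumours. In 2-sided exact permutation tests each had p = 0.009524, the smallest that 4 against 6 tumours can give. With Benjamini-Hochberg adjustment over the 10 pairs of groups the exact permutation adjusted p was 0.0318. Cobimetinib lay −0.63 from Vehicle, with 3 of 4 tumours below all Vehicle tumours (exact permutation p = 0.0286, adjusted p = 0.0408). RMC-7977, RMC-4550 and trametinib lay −1.52, −0.87 and −0.95 from cobimetinib, each with all 4 tumours below all 4 cobimetinib tumours (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0408). RMC-7977 lay −0.65 from RMC-4550 (exact permutation p = 0.0571, adjusted p = 0.0714) and −0.56 from trametinib (p = 0.2, adjusted p = 0.222). RMC-4550 and trametinib differed by 0.08 (exact permutation p = 0.857), so the score did not separate these 3 drugs. Without any 1 cobimetinib tumour, or without Vehicle replicate 3, 5, 6 or 7, the adjusted p of cobimetinib against Vehicle was 0.0595 to 0.0893, at differences of −0.52 to −0.71. The contrasts with cobimetinib lost their call without any 1 tumour of either group (adjusted p = 0.0635 to 0.0816), where 3 against 4 tumours cannot give an exact permutation p below 0.0571. Without Trametinib replicate 4 trametinib lay −0.57 from cobimetinib, RMC-7977 −0.95 from trametinib, all 4 tumours below the other 3 (adjusted p = 0.0635), and RMC-4550 turned to −0.30 from trametinib (adjusted p = 0.343). Paired by replicate number, RMC-4550 and trametinib lay −1.27 and −0.93 from Vehicle (3 pairs each, too few to pass).

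**Figure D1:**
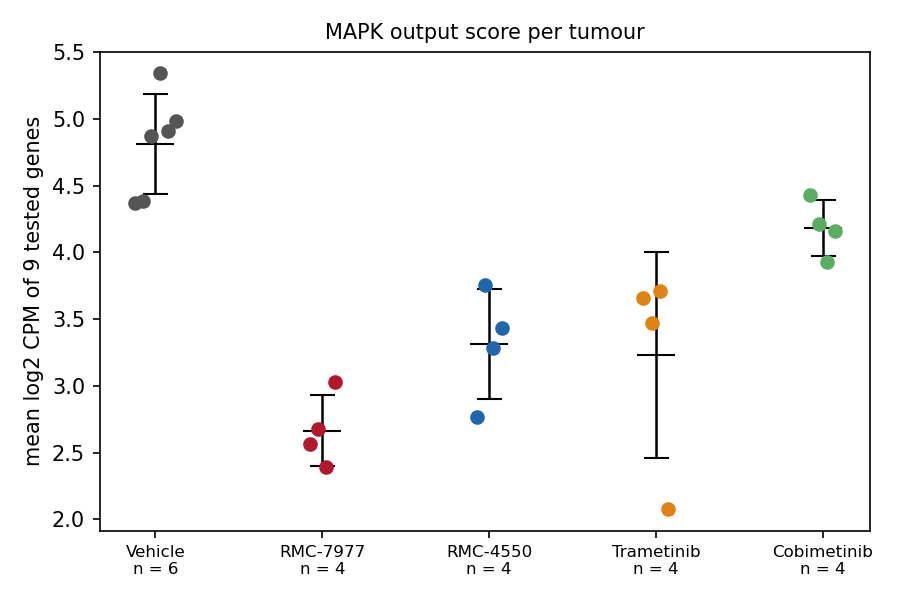
MAPK output score of each tumour (vertical axis, mean log2 CPM of the 9 tested genes) by treatment group (horizontal axis), with points for tumours and lines for the group mean and SD. The 4 RMC-7977 tumours lay between 2.39 and 3.03, the 6 Vehicle tumours between 4.37 and 5.34, and Trametinib replicate 4 at 2.08.

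RMC-7977 lowered the ERK-responsive transcription factor genes ETV4 and ETV5, MILR1 and PTGS1, and raised TSC22D3 and SOCS2. ETV4 (ENSG00000175832, hg38 chromosome 17, 43527844 to 43579620) went from 18.5 ± 8.51 CPM under Vehicle to 0.803 ± 0.357 CPM (SD, 6 and 4 tumours), a log2 fold change of −4.49 ± 0.58 (SE). ETV5 (ENSG00000244405, chromosome 3, 186046308 to 186110318) fell by 2.71 ± 0.38 on the log2 scale. The other large falls were of the cell-surface receptor gene MILR1 (−3.73 ± 0.64; ENSG00000271605, chromosome 17, 64449037 to 64468643) and of PTGS1, which encodes the prostaglandin-forming enzyme cyclooxygenase 1 (−2.97 ± 0.33; ENSG00000095303, chromosome 9, 122370530 to 122395703). CYP24A1, which inactivates vitamin D (−2.97 ± 0.40; ENSG00000019186, chromosome 20, 54153449 to 54173973), and the secreted hormone gene STC1 (−2.85 ± 0.45; ENSG00000159167, chromosome 8, 23841915 to 23854807) also fell. TSC22D3, a glucocorticoid-induced transcriptional regulator, rose from 121 ± 42.9 to 468 ± 84.7 CPM (log2 fold change 1.96 ± 0.25; ENSG00000157514, chromosome X, 107713221 to 107777342). SOCS2, a suppressor of cytokine signalling, rose from 4.17 ± 1.26 to 14.7 ± 2.72 CPM (1.81 ± 0.28; ENSG00000120833, chromosome 12, 93569814 to 93583487). FAM177B (1.63 ± 0.27), P3H2, a collagen prolyl hydroxylase (1.44 ± 0.23), HDAC9, a histone deacetylase (1.70 ± 0.32), and the mucin gene MUC15 (1.61 ± 0.33) also rose. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 12 genes had adjusted p between 0.000169 (PTGS1) and 0.0194 (MUC15), with all 4 treated tumours on one side of all 6 Vehicle tumours. HDAC9 lost its call without RMC-7977 replicate 1 (edgeR quasi-likelihood adjusted p = 0.0639), and MUC15 without Vehicle replicate 5 or RMC-7977 replicate 1, 2 or 3 (0.0515 to 0.0966).

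**Figure D2:**
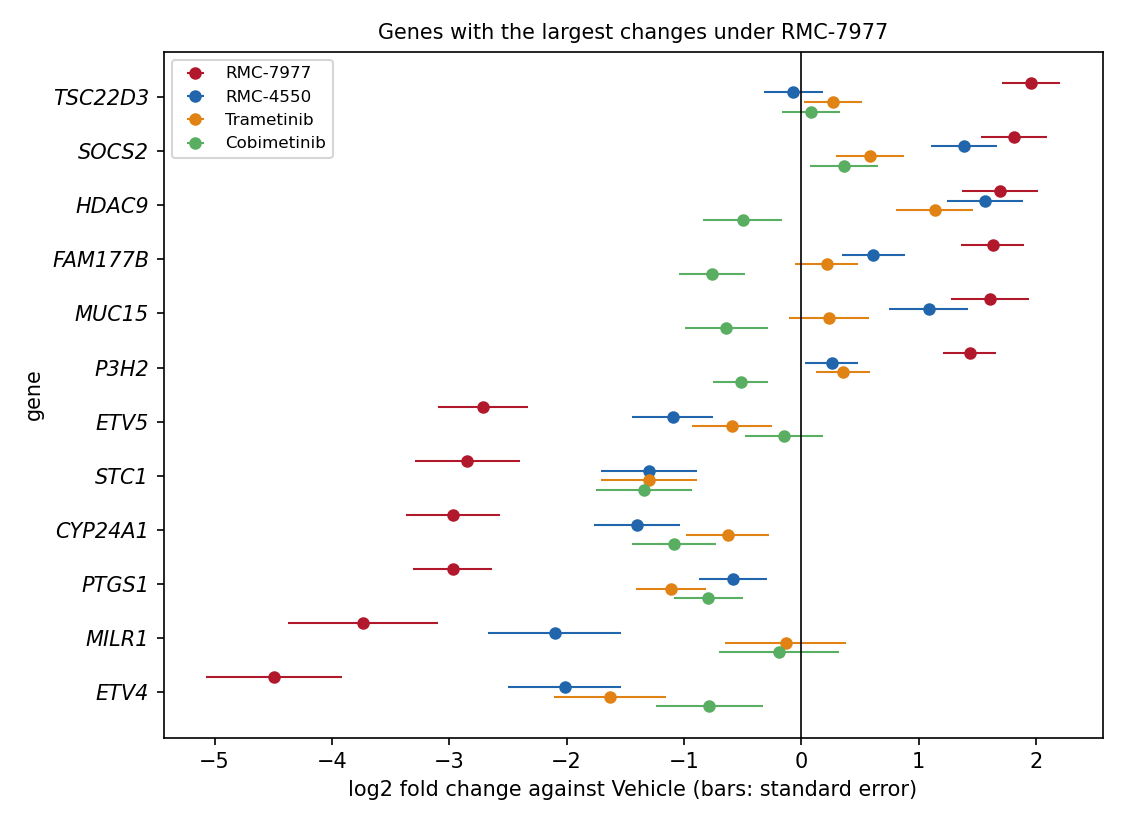
Log2 fold change against Vehicle (horizontal axis, points with SE bars) of the 12 genes named for RMC-7977 (vertical axis) in each of the 4 drug groups. ETV4 stands at −4.49 under RMC-7977, −2.02 under RMC-4550, −1.63 under trametinib and −0.78 under cobimetinib, and TSC22D3 at 1.96, −0.07, 0.27 and 0.08.

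In all, 132 genes passed the threshold for RMC-7977 against Vehicle, 53 higher and 79 lower, and 108 of them by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 1824 genes where chance gives 883. The count was 541 without Trametinib replicate 4, a tumour of neither group, 369 without the 2 libraries with few low counts and 1134 without the 4 libraries apart. Among single tumours of the 2 groups, the count was 217 without Vehicle replicate 1, 245 without Vehicle replicate 2 and 63 without Vehicle replicate 5. It was 43, 53, 87 and 72 without RMC-7977 replicates 1, 2, 3 and 4.

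Among the ERK-responsive MAPK output genes, 6 of 9 fell under RMC-7977 and 3 did not pass, with 7 lower when adjusted over the list alone. Beside ETV4 and ETV5 these were DUSP6, the phosphatase that switches off ERK (−3.69 ± 0.54, from 18.5 ± 6.59 to 1.42 ± 0.309 CPM; ENSG00000139318, chromosome 12, 89347232 to 89353271), and PHLDA1 (−2.83 ± 0.44). The phosphatase gene DUSP4 (−1.73 ± 0.29) and SPRY4, a feedback inhibitor of receptor signalling (−3.40 ± 0.65), completed the 6, all with edgeR quasi-likelihood adjusted p of 0.0122 or less. SPRY2 (−0.64 ± 0.18), CCND1 (−0.46 ± 0.31) and EPHA2 (−0.50 ± 0.42) did not pass, but SPRY2 did without Trametinib replicate 4 (0.019). SPRY4 lost its call without RMC-7977 replicate 1 (edgeR quasi-likelihood adjusted p = 0.0639) or 2 (0.0669). The list as a whole was lower than the other genes by camera (adjusted p = 1.34e-26, and adjusted p = 0.000173 with an estimated correlation). Of the 13 tested immediate early genes, which growth factor signals induce, 3 fell, 10 did not pass, and 5 were lower when adjusted over the list alone. EGR1 (−3.67 ± 0.76), FOSL1 (−2.85 ± 0.64) and IER3 (−1.42 ± 0.30) fell, and MYC did not pass (−0.87 ± 0.21, edgeR quasi-likelihood adjusted p = 0.0556). Their camera adjusted p of 8.07e-05 became adjusted p = 0.316 with an estimated correlation. EGR1 lost its call without RMC-7977 replicate 1, 2 or 3 (highest adjusted p 0.107) and IER3 without Vehicle replicate 5, 6 or 7 or RMC-7977 replicate 1, 3 or 4 (highest 0.121). FOSL1 lost its call without Vehicle replicate 5, 6 or 7 or any 1 RMC-7977 tumour (highest 0.167). MYC passed without Vehicle replicate 2 (0.0345) or 6 (0.0428), RMC-7977 replicate 3 (0.0465) or Trametinib replicate 4 (0.016).

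Most genes of the targeted pathway did not pass under RMC-7977, but GAB1 rose and SPRED1 fell. RIT1 (ENSG00000143622, chromosome 1, 155897808 to 155911404) was expressed at 118 ± 17.1 CPM under Vehicle and 145 ± 14.8 CPM under RMC-7977 (log2 fold change 0.29 ± 0.17, edgeR quasi-likelihood adjusted p = 0.606). It did not pass under RMC-4550 (0.23 ± 0.17), trametinib (0.03 ± 0.17) or cobimetinib (0.02 ± 0.17). GAB1, a docking protein that recruits SHP2, lay at 0.84 ± 0.19 and SPRED1, an inhibitor of RAS activation, at −1.15 ± 0.22. GAB1 lost its call without Vehicle replicate 5, 6 or 7 or any 1 RMC-7977 tumour (highest adjusted p 0.107). SOS2, which loads RAS with GTP, did not pass (0.51 ± 0.15, edgeR quasi-likelihood adjusted p = 0.118), but did without Trametinib replicate 4 (0.0189). Nor did any of NRAS (0.26 ± 0.29), HRAS (−0.11 ± 0.16), PTPN11 (−0.11 ± 0.20), MAP2K1 (0.20 ± 0.17) and MAP2K2 (0.19 ± 0.21) pass. Of the 27 tested RAS pathway genes 2 rose, 1 fell and 24 did not pass, with 4 higher and 1 lower when adjusted over the list alone. By camera the list (up) had adjusted p = 0.0168, but adjusted p = 0.494 with an estimated correlation.

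Of the EGF receptor ligand genes AREG and EREG fell under RMC-7977. AREG went from 25.4 ± 18.3 to 6.45 ± 1.67 CPM (−1.98 ± 0.41) and EREG from 46.2 ± 24.5 to 12.2 ± 4.72 CPM (−1.92 ± 0.44). HBEGF (−1.46 ± 0.44) and BTC (0.34 ± 0.24) did not pass, but HBEGF did without Vehicle replicate 2 (0.0442) or Trametinib replicate 4 (0.0368). Of 7 tested ligands 2 fell and 5 did not pass, with 3 lower when adjusted over the list alone. Camera gave the list adjusted p = 0.0423, and adjusted p = 0.37 with an estimated correlation. The camera call ended without Vehicle replicate 1 (0.242), RMC-7977 replicate 1, 2 or 4 (0.0622 to 0.0998) or Trametinib replicate 4 (0.082). AREG lost its own call without any 1 RMC-7977 tumour (0.0545 to 0.107) and EREG without Vehicle replicate 5, 6 or 7 or RMC-7977 replicate 1, 2 or 4 (0.0536 to 0.139). Among 17 tested receptor tyrosine kinases AXL fell (−1.53 ± 0.36, edgeR quasi-likelihood adjusted p = 0.0455), and 16 did not pass. Of the 17, 1 was lower when adjusted over the list alone, and the class as a whole was not called (camera adjusted p = 0.284). AXL lost its call without Vehicle replicate 3, 5, 6 or 7 or any 1 RMC-7977 tumour (0.0561 to 0.201).

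Genes of cell growth and division leaned lower under RMC-7977. Of 24 DNA replication genes RRM2, a subunit of ribonucleotide reductase (−0.94 ± 0.20), and the replication origin factor MCM10 (−1.14 ± 0.24) fell. The other 22 did not pass. In all 2 were lower when adjusted over the list alone, and 21 of the 24 had negative log2 fold changes. As a list, by camera, they (down) had adjusted p = 8.14e-06, and adjusted p = 0.316 with an estimated correlation. RRM2 lost its call without Vehicle replicate 5 or RMC-7977 replicate 1, 2 or 4 (edgeR quasi-likelihood adjusted p = 0.065 to 0.107), and MCM10 without Vehicle replicate 5 or any 1 RMC-7977 tumour (0.0515 to 0.121). None of the 21 ribosome biogenesis genes passed, with 1 lower when adjusted over the list alone, NOP56 (−0.56 ± 0.15, edgeR quasi-likelihood adjusted p = 0.0778). Tested together by camera the list (down) had adjusted p = 8.07e-05, and adjusted p = 0.368 with an estimated correlation. NOP56 passed without Trametinib replicate 4 (0.00982). None of the 24 mitosis genes passed either way of adjusting, with a median log2 fold change of −0.26. For the list, camera (down) gave adjusted p = 0.00624, and adjusted p = 0.622 with an estimated correlation. That camera call ended without Vehicle replicate 1 (0.183) or RMC-7977 replicate 1 (0.0665) or 4 (0.0562).

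Cholesterol synthesis genes leaned higher and inflammatory and mesenchymal genes lower. INSIG1 (1.02 ± 0.24, edgeR quasi-likelihood adjusted p = 0.0447) was the only gene of 22 on the cholesterol synthesis list to rise over all genes tested and over the list alone. The other 21 did not pass, but 20 of the 22 had positive log2 fold changes, with a median of 0.42. Over this list camera (up) gave adjusted p = 8.14e-06, and adjusted p = 0.37 with an estimated correlation. INSIG1 lost its call without Vehicle replicate 5, 6 or 7 or RMC-7977 replicate 2, 3 or 4 (0.0644 to 0.135). All 13 tested NF-kB and inflammatory cytokine genes had negative log2 fold changes, with a median of −0.85, and none passed over all genes tested. Among them 2 were lower when adjusted over the list alone, IL6 (−3.08 ± 0.94) and the neutrophil-attracting chemokine gene CXCL2 (−1.63 ± 0.54). IL6 passed over all genes without Vehicle replicate 2 (0.0498) and CXCL2 without Trametinib replicate 4 (0.0132). Their camera adjusted p of 0.000173 became adjusted p = 0.153 with an estimated correlation. Of 8 tested mesenchymal genes none passed either way of adjusting, TNC (−1.49 ± 0.50) among them. Camera on the list (down) gave adjusted p = 0.00148, and adjusted p = 0.37 with an estimated correlation. Without the 2 libraries with few low counts the camera adjusted p was 0.0546.

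The fatty acid receptor CD36, on the alveolar type 2 list, rose under RMC-7977 from 91.2 ± 34.2 to 214 ± 20.6 CPM (1.23 ± 0.28, edgeR quasi-likelihood adjusted p = 0.0379). It lost its call without Vehicle replicate 3, 5 or 6 or any 1 RMC-7977 tumour (0.0754 to 0.11). It was the only gene of 11 tested type 2 genes to pass, over all genes and over the list alone, and the list went no one way. Its median was −0.33, its mean −0.004 and its camera direction up (camera adjusted p = 0.265). The list was called without Vehicle replicate 6 (0.0277) or RMC-7977 replicate 3 (0.0359). The sources do not say whether host reads were removed, so markers of myeloid, endothelial, muscle and blood cells, here and below, may hold host reads counted as human. Members of these lists with too few counts were not tested. Markers of myeloid cells were lower, and LAPTM5 fell from 5.40 ± 3.16 to 0.395 ± 0.442 CPM (−3.76 ± 0.66). The other 7 of 8 tested markers did not pass, and 3 were lower when adjusted over the list alone, with CD14 (−0.96 ± 0.36). The myeloid list was called by camera (adjusted p = 0.000877, and adjusted p = 0.0232 with an estimated correlation). Of 7 tested endothelial markers PECAM1 fell (−1.71 ± 0.36), 6 did not pass, and 1 was lower when adjusted over the list alone. With camera the list (down) had adjusted p = 0.0423, and adjusted p = 0.457 with an estimated correlation. The endothelial camera call ended without Vehicle replicate 1 (0.114) or 6 (0.0542), RMC-7977 replicate 1, 2 or 4 (0.0562 to 0.0645) or Trametinib replicate 4 (0.0777). PECAM1 lost its call without Vehicle replicate 5 or 7 or RMC-7977 replicate 1, 2 or 4 (0.0533 to 0.121).

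RMC-4550 lowered DUSP6 and raised CD36 and the growth factor gene BMP2. DUSP6 went from 18.5 ± 6.59 CPM under Vehicle to 1.60 ± 0.697 CPM (log2 fold change −3.52 ± 0.53, SE, 6 and 4 tumours), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p = 0.0191. CD36 (ENSG00000135218, chromosome 7, 80369575 to 80679277) rose to 279 ± 143 CPM (1.61 ± 0.28), and BMP2 (ENSG00000125845, chromosome 20, 6767664 to 6780280) rose from 40.5 ± 3.45 to 87.8 ± 28.4 CPM (1.11 ± 0.18). MYEOV (ENSG00000172927, chromosome 11, 69294138 to 69367726), a gene overexpressed in myeloma, fell by 0.99 ± 0.17, and all 3 had an edgeR quasi-likelihood adjusted p of 0.0326. The noncoding gene AJ009632.2 (ENSG00000229425, chromosome 21, 15370500 to 15627342), outside the naming rule and chosen after its values were seen, was the remaining call (2.15 ± 0.37, edgeR quasi-likelihood adjusted p = 0.0326). These 5 genes, 3 higher and 2 lower, were all that passed, with 749 genes at an unadjusted p under 0.05 where chance gives 883. The count was 11 without Trametinib replicate 4, 13 without the 2 libraries with few low counts and 11 without the 4 libraries apart. It was 3, 1, 2, 0, 3 and 2 without Vehicle replicates 1, 2, 3, 5, 6 and 7, and 0, 4, 0 and 4 without RMC-4550 replicates 1 to 4. DUSP6 lost its call without Vehicle replicate 5 (0.071) or RMC-4550 replicate 1 (0.143) or 3 (0.131), and CD36 without Vehicle replicate 2, 3, 5 or 6 or RMC-4550 replicate 1 or 3 (0.0633 to 0.405). BMP2 lost its call without Vehicle replicate 2, 3, 5, 6 or 7 or RMC-4550 replicate 1, 2 or 3 (0.0528 to 0.227) and MYEOV without Vehicle replicate 1, 2, 3, 5 or 7 or RMC-4550 replicate 1, 3 or 4 (0.0621 to 0.264). With the replicate number as a block none passed (598 at an unadjusted p under 0.05), DUSP6 (−3.08), CD36 (1.60) and MYEOV (−1.09) being at adjusted p = 0.403 and BMP2 (1.03) at 0.869. The counts of 0 are by edgeR's quasi-likelihood test, DESeq2 called 34 genes on all 22 tumours, and with only the 2 groups, or against a log2 fold change of 0.5, 1 passed.

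All 9 tested MAPK output genes had negative log2 fold changes under RMC-4550. DUSP6 fell and 8 did not pass over all genes tested. Adjusted over the list alone, 7 were lower, with PHLDA1 at −1.91 ± 0.41, SPRY4 at −2.56 ± 0.61 and ETV4 at −2.02 ± 0.48. By camera the list had adjusted p = 4.06e-25, and adjusted p = 0.000193 with an estimated correlation. SPRY4 passed over all genes without Trametinib replicate 4 (adjusted p = 0.0353). NRF2 targets, the oxidative stress enzymes, had 15 of 16 positive log2 fold changes with a median of 0.41, and none passed over all genes. Among them 3 were higher when adjusted over the list alone, GCLM (0.81 ± 0.27), AKR1B10 (0.92 ± 0.30) and AKR1C3 (0.88 ± 0.30). Their camera adjusted p of 6.84e-08 became adjusted p = 0.155 with an estimated correlation. The tested immediate early genes (13), epithelial genes (17), mesenchymal genes (8), mitosis genes (24) and glycolysis genes (17) held no gene that passed. Their median log2 fold changes were −0.34, −0.20, −0.55, −0.20 and −0.23. Adjusted over the list alone, 1 immediate early gene was higher (ATF3, 0.88 ± 0.22) and 5 lower, and no gene of the other 4 lists passed. Their camera adjusted p were 0.0142, 0.00697, 0.00374, 0.00772 and 0.0199, all down, and in the same order adjusted p = 0.691, 0.742, 0.657, 0.76 and 0.691 with an estimated correlation. Leaving out RMC-4550 replicate 1 ended the camera calls of 4 of them (immediate early 0.148, epithelial 0.208, mesenchymal 0.148, glycolysis 0.208). The immediate early call also ended without Vehicle replicate 5 or RMC-4550 replicate 3 (0.0567, 0.211), and the epithelial call without Vehicle replicate 2 (0.0576). The mitosis call ended without Vehicle replicate 1 or 5 or RMC-4550 replicate 4 (0.493, 0.0537, 0.532), and that of glycolysis without Vehicle replicate 1 (0.0562). CD36 alone passed of 11 tested alveolar type 2 genes, over all genes and over the list alone. The median (−0.07) and mean (−0.12) of that list were negative and its camera direction up (camera adjusted p = 0.552, and 0.047 without Vehicle replicate 6). The skeletal muscle markers, a sign of other tissue, held 4 tested genes, of which none passed over all genes and MB (0.90 ± 0.24) was higher when adjusted over the list alone. Camera gave the list (up) adjusted p = 0.0451, and adjusted p = 0.415 with an estimated correlation. This call ended without Vehicle replicate 1, 2, 5 or 7 or RMC-4550 replicate 1 or 4 (0.0508 to 0.14). With the replicate block the camera calls of immediate early (0.603), mitosis (0.306), glycolysis (0.0701) and skeletal muscle genes (0.358) ended.

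Under trametinib the ERK-responsive genes stood lower than under Vehicle, but no single gene passed. DUSP6 went from 18.5 ± 6.59 to 2.55 ± 1.79 CPM (log2 fold change −2.80 ± 0.51), and DUSP4 from 418 ± 64.3 to 173 ± 77.4 CPM (−1.27 ± 0.29). SPRY4 lay at −2.35 ± 0.60 and EPHA2, a receptor kinase gene, at −1.57 ± 0.44, and the 4 had adjusted p of 0.0663 to 0.0958 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 9 MAPK output genes 8 were lower when adjusted over the list alone. As a list, by camera, they had adjusted p = 2.79e-10, and adjusted p = 0.0291 with an estimated correlation. DUSP6 passed without Vehicle replicate 1 or 2 or any 1 trametinib tumour (0.0121 to 0.047), and DUSP4 without Vehicle replicate 1 or Trametinib replicate 1, 2 or 3 (0.0133 to 0.047). SPRY4 passed without Vehicle replicate 1 or Trametinib replicate 1 or 3 (0.0238 to 0.047). EPHA2 (0.0312 to 0.047) and ETV4 (0.0421 to 0.047) passed without Vehicle replicate 1 or Trametinib replicate 3, and PHLDA1 without Vehicle replicate 1 (0.0497). The smallest adjusted p of any gene was 0.0504, for DUSP5, an ERK phosphatase (−1.79), named after its values were seen. The edgeR quasi-likelihood count was 0 genes, with 3327 at an unadjusted p under 0.05 where chance gives 883, and DESeq2 called 393. The count was 1 without Trametinib replicate 4, 1 without the 2 libraries with few low counts and 2686 without the 4 libraries apart. It was 740, 3 and 2 without Vehicle replicates 1, 2 and 6, and 548, 625 and 1428 without Trametinib replicates 1, 2 and 3, each of which leaves Trametinib replicate 4 in. With the replicate number as a block it was 0, with 369 at an unadjusted p under 0.05.

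Of 13 tested immediate early genes none passed under trametinib, and 7 were lower when adjusted over the list alone. Nearest were JUNB (−1.53 ± 0.32) and IER3 (−1.40 ± 0.30). Tested together by camera the list (down) had adjusted p = 0.000677, and adjusted p = 0.534 with an estimated correlation. Over all genes JUNB and IER3 passed without Vehicle replicate 1 or Trametinib replicate 1, 2 or 3 (edgeR quasi-likelihood adjusted p = 0.0157 to 0.047). Of 13 NF-kB and cytokine genes none passed over all genes and the chemokine gene CXCL3 (−1.77 ± 0.50) was lower when adjusted over the list alone. For the list, camera (down) gave adjusted p = 0.00645, and adjusted p = 0.534 with an estimated correlation. CXCL3 passed without Vehicle replicate 1 (0.047) or Trametinib replicate 3 (0.0142). None of 18 YAP/TEAD targets passed either way of adjusting, with 16 negative log2 fold changes. Over this list camera (down) gave adjusted p = 0.0118, and adjusted p = 0.648 with an estimated correlation. Alveolar type 2 genes had a median of 0.95 over 11 tested genes. None passed over all genes and SFTPD, a surfactant protein gene (1.18 ± 0.32), was higher when adjusted over the list alone. Camera on the list (up) gave adjusted p = 0.0392, and adjusted p = 0.536 with an estimated correlation. That camera call ended without Vehicle replicate 1 (0.212) or Trametinib replicate 3 (0.297), and SFTPD itself passed without them (0.047 and 0.0286). Epithelial genes (17 tested, none passed either way of adjusting, median −0.27) had a camera adjusted p of 0.0427 and adjusted p = 0.648 with an estimated correlation. They lost the call without Vehicle replicate 1, 2 or 7 or Trametinib replicate 1, 2 or 4 (0.0512 to 0.136). Among markers of other tissue, CDH5 (3.25 ± 0.92), VWF (2.22 ± 0.70) and TEK (2.08 ± 0.79) of 7 endothelial genes were higher when adjusted over the list alone, as were MYLPF (2.52 ± 0.76) and NEB (0.95 ± 0.38) of 4 skeletal muscle genes. None passed over all genes, and neither list was called (camera adjusted p = 0.291 and 0.108). CDH5, VWF and MYLPF passed without Trametinib replicate 1, 2 or 3 (0.0194 to 0.0495) and TEK without replicate 3 (0.0432), but without replicate 4 the 4 turned to −0.04, −0.25, −0.15 and −0.13. The mitochondrially encoded genes, a sign of RNA quality, had 12 of 13 negative log2 fold changes with a median of −0.39, and none passed either way of adjusting. With camera the list (down) had adjusted p = 0.0392, and adjusted p = 0.648 with an estimated correlation. This call ended without Trametinib replicate 4 (0.678) or Vehicle replicate 2, 3 or 6 (0.0548 to 0.0823). With the replicate block it ended too (0.135), as did that of the YAP/TEAD targets (0.0964).

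By median absolute log2 fold change against Vehicle (0.165) cobimetinib changed least of the 4 drugs, but not by calls with library weights. The pathway genes PHLDA1, from 9.58 ± 4.86 to 2.71 ± 1.15 CPM (log2 fold change −1.82 ± 0.41), and DUSP6, from 18.5 ± 6.59 to 5.81 ± 1.33 CPM (−1.67 ± 0.47), stood lower. By edgeR's quasi-likelihood test neither passed over all genes (adjusted p = 0.898 and 0.912). Adjusted over the list alone, 3 of the 9 MAPK output genes were lower, and SPRY2 (−0.20 ± 0.18) and SPRY4 (−0.20 ± 0.53) were not. By camera the list (down) had adjusted p = 1.26e-06, and adjusted p = 0.142 with an estimated correlation. The edgeR quasi-likelihood count was 0 genes, with 582 at an unadjusted p under 0.05 where chance gives 883, and DESeq2 called 1. It was 2 without Trametinib replicate 4, 0 without the 2 libraries with few low counts and 8 without the 4 libraries apart. Amino acid stress genes, the targets of the transcription factor ATF4, leaned higher, with 15 of 19 positive log2 fold changes and none past the threshold over all genes. Adjusted over the list alone, 3 were higher, SESN2 (0.91 ± 0.23) among them. Camera gave the list (up) adjusted p = 0.000109, and adjusted p = 0.286 with an estimated correlation. Lists that leaned lower were DNA replication (24 tested, median −0.27), FOXO and PI3K feedback (12, −0.33) and hypoxia (17, −0.33). Others were glycolysis (17, −0.27), epithelial identity (17, −0.26, KRT8 at −0.73 ± 0.22), NRF2 targets (16, −0.19) and immediate early genes (13, −0.18). No member of these 7 passed over all genes, and adjusted over the list alone 2 epithelial genes and 1 immediate early gene were lower. Their camera adjusted p, in that order, were 0.000101, 0.000112, 0.000112, 0.000551, 0.000101, 0.00229 and 0.04. All 7 camera calls were lost, at adjusted p = 0.304, 0.286, 0.312, 0.286, 0.312, 0.312 and 0.484 with an estimated correlation. The immediate early call ended without Vehicle replicate 3, 5, 6 or 7, Trametinib replicate 4, or Cobimetinib replicate 3 or 4 (0.0699 to 0.515), and that of glycolysis without Cobimetinib replicate 3 (0.191). The 4 tested skeletal muscle markers, none passing either way, had a median of 0.53. Camera (up) gave adjusted p = 0.04, and adjusted p = 0.286 with an estimated correlation. Their call was lost without Vehicle replicate 2, 3, 5 or 7 or Cobimetinib replicate 3 or 4 (0.0555 to 0.191).

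Compared directly, RMC-7977 tumours held more TSC22D3 and less PTGS1, HAL and BDNF than RMC-4550 tumours. TSC22D3 was at 468 ± 84.7 against 115 ± 18.6 CPM (log2 fold change 2.02 ± 0.28, SE, 4 and 4 tumours), and HAL, the histidine-degrading enzyme, at 12.3 ± 3.94 against 53.7 ± 5.10 CPM (−2.12 ± 0.31; ENSG00000084110, chromosome 12, 95972662 to 95996365). PTGS1 lay at −2.39 ± 0.34, and BDNF, a neurotrophin gene, at −1.73 ± 0.26 (ENSG00000176697, chromosome 11, 27654893 to 27722058), and all 4 had an adjusted p of 0.00426 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The endothelial and lung transcription factor gene KLF2 (2.95 ± 0.54, edgeR quasi-likelihood adjusted p = 0.0265; ENSG00000127528, chromosome 19, 16324817 to 16327874) and FAXDC2 (1.47 ± 0.29, adjusted p = 0.0458; ENSG00000170271, chromosome 5, 154818491 to 154859252) were also higher. Both lost their calls without RMC-7977 replicate 1, 2 or 4 or any 1 RMC-4550 tumour (0.0712 to 0.204). In all, 16 genes passed, 6 higher and 10 lower, with 1305 at an unadjusted p under 0.05 where chance gives 883. There were 105 without Trametinib replicate 4, 133 without the 2 libraries with few low counts and 192 without the 4 libraries apart. The count was 8, 10, 28 and 10 without RMC-7977 replicates 1 to 4 and 10 without RMC-4550 replicate 2.

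NRF2 targets leaned lower and cholesterol synthesis genes higher under RMC-7977 than under RMC-4550. Of the NRF2 targets 15 of 16 had negative log2 fold changes and none passed over all genes. Among them 6 were lower when adjusted over the list alone, such as the aldo-keto reductases AKR1C1 (−1.37 ± 0.30) and AKR1B10 (−1.43 ± 0.34). The AKR1C genes are closely alike in sequence, so their counts are uncertain. Tested together by camera the list had adjusted p = 3.29e-07, and adjusted p = 0.207 with an estimated correlation. AKR1C1 and AKR1B10 passed without Trametinib replicate 4 (edgeR quasi-likelihood adjusted p = 0.0235 and 0.049). Cholesterol synthesis genes had 21 of 22 positive log2 fold changes and none past the threshold over all genes. Among them 2 were higher when adjusted over the list alone. For the list, camera gave adjusted p = 3.29e-07, and adjusted p = 0.385 with an estimated correlation. None of the 9 MAPK output genes passed over all genes and 3 were lower when adjusted over the list alone, ETV4 (−2.48 ± 0.57) and ETV5 (−1.62 ± 0.39) among them. Over this list camera gave adjusted p = 0.00179, and adjusted p = 0.385 with an estimated correlation. ETV4 passed over all genes without Trametinib replicate 4 (0.0269) and ETV5 without RMC-7977 replicate 4 (0.0456). NF-kB and cytokine genes (13 tested, median −0.62), DNA replication genes (24, −0.22) and epithelial genes (17, 0.21, the keratin gene KRT19 at 1.25 ± 0.26) held no gene that passed over all genes. When adjusted over the list alone they held 3 lower, 2 lower and 1 higher. By camera the 3 had adjusted p of 4.1e-05, 0.000833 and 0.000833, and adjusted p = 0.207, 0.563 and 0.563 with an estimated correlation. KRT19 passed without RMC-7977 replicate 3 (0.0253) or Trametinib replicate 4 (0.0266).

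**Figure D3:**
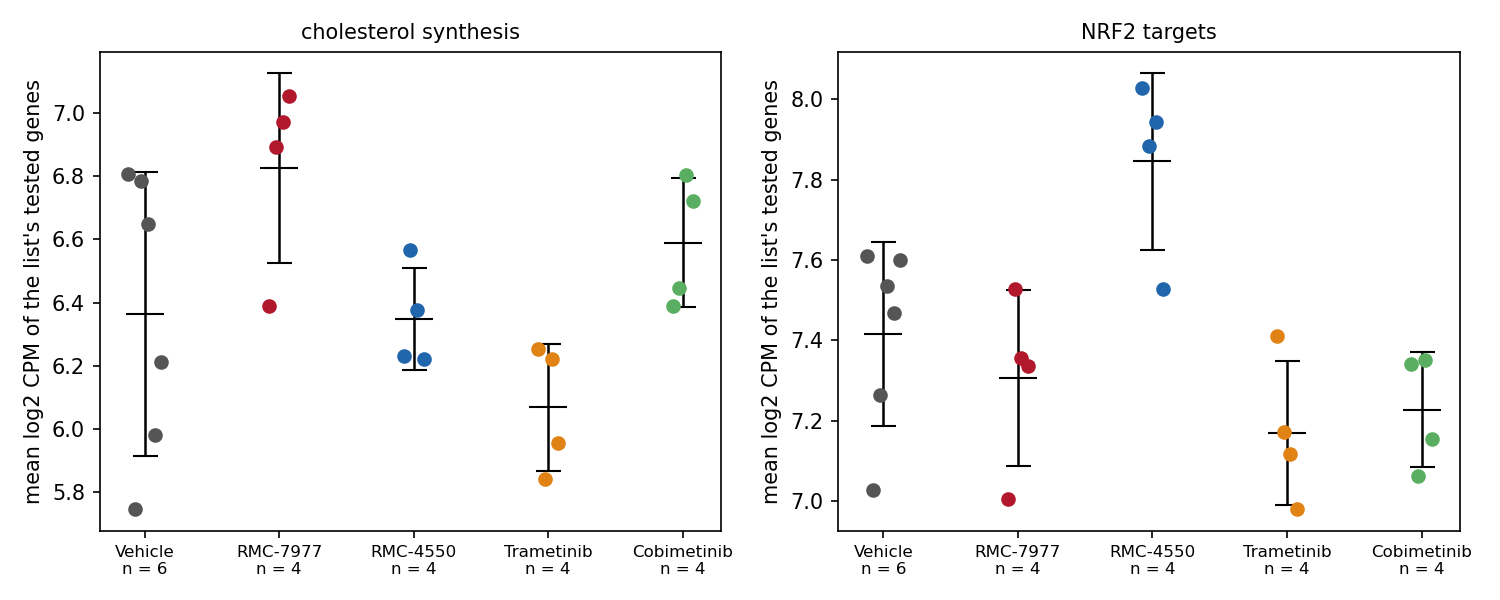
Mean log2 CPM of the tested genes (vertical axes) of the cholesterol synthesis list (left, 22 genes) and the NRF2 target list (right, 16 genes) in each tumour by treatment group (horizontal axes), with points for tumours and lines for the group mean and SD. Cholesterol synthesis stood at 6.83 ± 0.30 under RMC-7977 and 6.36 ± 0.45 under Vehicle, with overlapping tumours.

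Against trametinib, RMC-7977 tumours held more of the small heat shock protein gene HSPB1 and of TSC22D3 and less MILR1. HSPB1 (ENSG00000106211, chromosome 7, 76302544 to 76304295) was at 228 ± 71.9 against 70.5 ± 18.2 CPM (log2 fold change 1.69 ± 0.30), TSC22D3 at 468 ± 84.7 against 145 ± 43.2 CPM (1.69 ± 0.28). MVD, an enzyme of cholesterol synthesis, was higher too (1.48 ± 0.27; ENSG00000167508, chromosome 16, 88651935 to 88663161). MILR1 lay at −3.60 ± 0.66 and S100A2, a calcium-binding protein gene, at −3.20 ± 0.71 (ENSG00000196754, chromosome 1, 153561108 to 153567890). PROCR, the protein C receptor gene, lay at −2.63 ± 0.54 (ENSG00000101000, chromosome 20, 35172073 to 35216240). These 6 genes had adjusted p of 0.0271 to 0.0489 by edgeR's quasi-likelihood test. All 6 lost their call without RMC-7977 replicate 1, 2 or 4 (0.0762 to 0.162). MILR1, S100A2 and PROCR also lost theirs without replicate 3 (0.0506, 0.0892 and 0.067), and MVD, S100A2 and PROCR without Trametinib replicate 4 (0.0535, 0.3 and 0.128). In all, 72 genes passed, 22 higher and 50 lower, with 3205 at an unadjusted p under 0.05 where chance gives 883. There were 28 (13 higher) without Trametinib replicate 4, 42 without the 2 libraries with few low counts and 941 without the 4 libraries apart. The count was 0, 0, 22 (12 higher) and 2 without RMC-7977 replicates 1 to 4. It was 420, 607 and 1288 (35, 55 and 216 higher) without Trametinib replicates 1, 2 and 3. With only the 2 groups, or against a log2 fold change of 0.5, none passed (1427 and 1814 at an unadjusted p under 0.05). The counts of 0 are by edgeR's quasi-likelihood test, and DESeq2 called 859 genes on all 22 tumours.

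Of 22 cholesterol synthesis genes MVD and INSIG1 (1.33 ± 0.27) were higher under RMC-7977 than under trametinib and 20 did not pass. Of the 22, 8 were higher when adjusted over the list alone. Camera on the list gave adjusted p = 8.23e-08, and adjusted p = 0.636 with an estimated correlation. INSIG1 lost its call without any 1 RMC-7977 tumour (0.0737 to 0.108) or Trametinib replicate 4 (0.0757). Of the 9 MAPK output genes ETV5 (−2.12 ± 0.40) and ETV4 (−2.87 ± 0.58) were lower, 7 did not pass, and 3 were lower when adjusted over the list alone. With camera the list had adjusted p = 0.0103, and adjusted p = 0.636 with an estimated correlation. ETV4 lost its call without any 1 RMC-7977 tumour (0.0784 to 0.13), ETV5 without RMC-7977 replicate 1, 2 or 3 or Trametinib replicate 4 (0.0627 to 0.104). The list's camera call ended without Trametinib replicate 3 (0.0989). None of 24 mitosis genes passed either way of adjusting, with 22 negative log2 fold changes. By camera the list had adjusted p = 0.00032, and adjusted p = 0.636 with an estimated correlation. Of 8 myeloid markers LAPTM5 was lower (−3.65 ± 0.68), 7 did not pass and 3 were lower when adjusted over the list alone. Camera gave the list adjusted p = 0.00343, and adjusted p = 0.0635 with an estimated correlation. LAPTM5 lost its call without RMC-7977 replicate 1, 2 or 4 (0.0825 to 0.103). Of 7 endothelial markers PECAM1 was lower (−1.92 ± 0.39), 6 did not pass and 3 were lower when adjusted over the list alone. As a list, by camera, they had adjusted p = 0.0116, and adjusted p = 0.636 with an estimated correlation. The call ended without Trametinib replicate 4 (0.376), and PECAM1 lost its own without that library (0.0867) or RMC-7977 replicate 1, 2 or 4 (0.11 to 0.128). None of 13 mitochondrially encoded genes passed either way of adjusting, all 13 having positive log2 fold changes with a median of 0.48. Tested together by camera the list had adjusted p = 0.0153, and adjusted p = 0.662 with an estimated correlation. This call ended without Trametinib replicate 4 (0.393).

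Against cobimetinib, RMC-7977 tumours held more FAM177B and less ETV4 and ETV5. FAM177B (ENSG00000197520, chromosome 1, 222737207 to 222750805) was at 53.2 ± 12.4 against 10.1 ± 2.07 CPM (log2 fold change 2.39 ± 0.31), ETV4 at 0.803 ± 0.357 against 10.8 ± 3.13 CPM (−3.71 ± 0.58). ETV5 was at 1.93 ± 1.21 against 11.6 ± 1.98 CPM (−2.57 ± 0.40). The 3 had adjusted p of 0.000988, 0.00446 and 0.00446 by edgeR's quasi-likelihood test. ALDH1A1, a retinaldehyde dehydrogenase gene (3.00 ± 0.53; ENSG00000165092, chromosome 9, 72900662 to 73080442), and the glycosyltransferase gene B3GNT6 (2.66 ± 0.58; ENSG00000198488, chromosome 11, 77034398 to 77041973) were higher and MILR1 lower (−3.54 ± 0.66). ALDH1A1 lost its call without RMC-7977 replicate 1 or 2 or Cobimetinib replicate 2, 3 or 4 (0.0544 to 0.074) and B3GNT6 without RMC-7977 replicate 1, 2 or 4 or any 1 cobimetinib tumour (0.102 to 0.196). MILR1 lost its call without RMC-7977 replicate 1, 2 or 4 or Cobimetinib replicate 2 or 3 (0.0559 to 0.0922). In all, 49 genes passed, 34 higher and 15 lower, with 1315 at an unadjusted p under 0.05 where chance gives 883. There were 202 without Trametinib replicate 4, 200 without the 2 libraries with few low counts and 674 without the 4 libraries apart. The count was 16, 20 and 24 without RMC-7977 replicates 1, 2 and 4, and 16, 14, 20 and 27 without Cobimetinib replicates 1 to 4.

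Of the 9 MAPK output genes 3 were lower under RMC-7977 than under cobimetinib, ETV4, ETV5 and SPRY4 (−3.20 ± 0.68). The other 6 did not pass, DUSP6 (−2.02 ± 0.54) among them, and 7 were lower when adjusted over the list alone. For the list, camera gave adjusted p = 5.99e-15, and adjusted p = 0.00405 with an estimated correlation. SPRY4 lost its call without RMC-7977 replicate 1, 2 or 3 or any 1 cobimetinib tumour (edgeR quasi-likelihood adjusted p = 0.0669 to 0.18), and DUSP6 passed without Trametinib replicate 4 (0.00517). PIK3IP1, an inhibitor of PI3K (1.38 ± 0.25, edgeR quasi-likelihood adjusted p = 0.0143), was higher among 12 FOXO and PI3K feedback genes. The other 11 did not pass, and 3 were higher when adjusted over the list alone, with TXNIP (1.33 ± 0.36). Over this list camera gave adjusted p = 0.000219, and adjusted p = 0.378 with an estimated correlation. Of 17 epithelial genes KRT19 was higher (1.34 ± 0.26), 16 did not pass and 1 was higher when adjusted over the list alone. Camera on the list gave adjusted p = 0.000219, and adjusted p = 0.454 with an estimated correlation. PIK3IP1 and KRT19 lost their calls without RMC-7977 replicate 1, 2 or 4 or Cobimetinib replicate 1, 2 or 3 (0.059 to 0.143). Amino acid stress genes (19 tested, median −0.53), NF-kB and cytokine genes (13, −0.66) and immediate early genes (13, −0.34) held none that passed over all genes. Adjusted over the list alone, 1 was lower in the first, none in the second, and 1 higher and 3 lower in the third. The 3 lists had camera adjusted p of 0.000258, 0.00059 and 0.0121, all down, and adjusted p = 0.378, 0.203 and 0.454 with an estimated correlation. The last of these calls ended without RMC-7977 replicate 3 (0.0816) or Cobimetinib replicate 2 (0.134).

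NRF2 targets leaned higher under RMC-4550 than under either MEK inhibitor. Against cobimetinib 15 of 16 NRF2 targets had positive log2 fold changes, and none passed over all genes. Among them 10 were higher when adjusted over the list alone, such as AKR1B10 (1.58 ± 0.34), NQO1 (1.01 ± 0.24), GCLC (0.74 ± 0.21) and TXNRD1 (0.88 ± 0.25). With camera the list had adjusted p = 5.61e-12, and adjusted p = 0.064 with an estimated correlation. The first 3 passed over all genes by edgeR's quasi-likelihood test without Trametinib replicate 4 (adjusted p = 0.0253 to 0.034). Against trametinib the same 15 of 16 count of positive values was seen, and none passed over all genes. Among them 8 were higher when adjusted over the list alone, such as ME1 (1.03 ± 0.29) and TXNRD1 (0.85 ± 0.25). By camera the list had adjusted p = 3.67e-08, and adjusted p = 0.273 with an estimated correlation. Against trametinib, 24 mitosis genes (median −0.26) and 13 NF-kB and cytokine genes (median 0.68) also held none that passed over all genes. When adjusted over the list alone they held none and 3 higher. These 2 lists had camera adjusted p of 0.000157 (down) and 0.000968 (up), and adjusted p = 0.696 and 0.287 with an estimated correlation. The mitosis call ended without Trametinib replicate 1 (0.057). For RMC-4550 against trametinib the edgeR quasi-likelihood count was 0 genes, with 2177 at an unadjusted p under 0.05 where chance gives 883, and DESeq2 called 191. The count was 0 without Trametinib replicate 4 and without the 2 libraries with few low counts, 64 without the 4 libraries apart, 41 without Trametinib replicate 3 and 2 without RMC-4550 replicate 3.

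Against cobimetinib 5 genes were higher under RMC-4550 and none lower. By the naming rule these were HDAC9 (log2 fold change 2.07 ± 0.37, from 2.79 ± 0.631 to 11.7 ± 1.69 CPM; ENSG00000048052, chromosome 7, 18086949 to 19002416) and SYTL2, a vesicle transport gene (1.49 ± 0.26; ENSG00000137501, chromosome 11, 85694224 to 85811159). The third was DKK1, a secreted WNT inhibitor (1.40 ± 0.23; ENSG00000107984, chromosome 10, 52314296 to 52318042). Outside the rule and chosen after their values were seen were STEAP4, a metalloreductase gene (1.36), and ARID5B, a transcriptional regulator (1.15). The 5 had adjusted p of 0.0138 to 0.0497 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 1095 genes where chance gives 883. There were 90 calls without Trametinib replicate 4, 100 without the 2 libraries with few low counts and 160 without the 4 libraries apart. The edgeR count was 3, 0 and 0 without RMC-4550 replicates 1, 2 and 4, and 0, 2, 0 and 0 without Cobimetinib replicates 1 to 4, DESeq2 called 138 genes on all 22 tumours, and none passed against a log2 fold change of 0.5 (415 at an unadjusted p under 0.05). HDAC9 lost its call without any 1 tumour of either group (0.0783 to 0.214) and SYTL2 without RMC-4550 replicate 1, 2 or 4 or any 1 cobimetinib tumour (0.0618 to 0.204). DKK1 lost its call without RMC-4550 replicate 2, 3 or 4 or any 1 cobimetinib tumour (0.0521 to 0.204). None of the 9 MAPK output genes passed over all genes, and SPRY4 (−2.36 ± 0.63) and DUSP6 (−1.85 ± 0.53) were lower when adjusted over the list alone. Camera gave the list adjusted p = 2.08e-06, and adjusted p = 0.0896 with an estimated correlation. Both passed over all genes without Trametinib replicate 4 (0.031 and 0.0174).

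The 2 MEK inhibitors, at their different doses, showed no single gene that separated them. SPRY4 stood at −2.14 ± 0.63 in trametinib against cobimetinib tumours. None of 9 MAPK output genes passed over all genes, and 1 was lower when adjusted over the list alone. As a list, by camera, they had adjusted p = 0.00427, and adjusted p = 0.454 with an estimated correlation. Amino acid stress genes had 16 of 19 negative log2 fold changes and none past the threshold over all genes. Among them 5 were lower when adjusted over the list alone, such as the pseudokinase gene TRIB3 (−1.11 ± 0.25) and SESN2 (−0.86 ± 0.26). Tested together by camera the list had adjusted p = 0.000558, and adjusted p = 0.454 with an estimated correlation. Cholesterol synthesis genes had 19 of 22 negative values and none past the threshold over all genes. Among them 4 were lower when adjusted over the list alone, such as MVD (−1.30 ± 0.27). For the list, camera gave adjusted p = 0.00193, and adjusted p = 0.896 with an estimated correlation. This camera call ended without Trametinib replicate 2 (0.0783). MVD, TRIB3 and SESN2 passed without Trametinib replicate 3 (edgeR quasi-likelihood adjusted p = 0.0476 each). All 13 mitochondrially encoded genes had negative values and none passed either way of adjusting. Their camera adjusted p of 0.044 (adjusted p = 0.948 with an estimated correlation) became 0.759 without Trametinib replicate 4 and 0.0513 to 0.13 without Trametinib replicate 1 or 2 or Cobimetinib replicate 1, 2 or 4. The edgeR quasi-likelihood count was 0 genes, with 2955 at an unadjusted p under 0.05 where chance gives 883, and DESeq2 called 114. It was 0 without Trametinib replicate 4 and without the 2 libraries with few low counts, 537 without the 4 libraries apart and 313 without Trametinib replicate 3.

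The log2 fold changes of the drugs against the shared Vehicle tumours were compared across the 17652 genes, which are not independent replicates. Pearson's r was 0.433 for RMC-7977 with RMC-4550, where unchanged groups simulated against the same Vehicle tumours gave 0.316 on average, and the covariance was 0.098 against 0.063 simulated. For RMC-7977 with cobimetinib r was 0.414 (0.315 simulated) and the covariance 0.0854 (0.0625), and for RMC-4550 with trametinib r was 0.308 (0.315) and the covariance 0.101 (0.0632). RMC-7977 with trametinib gave r = 0.188 (0.31 simulated) and a covariance of 0.0806 (0.0631), trametinib with cobimetinib 0.204 (0.313) and 0.061 (0.0628), and RMC-4550 with cobimetinib 0.276 (0.319) and 0.0434 (0.0625). All these values lay within the range of the 40 simulations, whose r went from 0.0977 to 0.7236 and covariance from 0.01235 to 0.3066 over the 6 pairs. With the Vehicle tumours split 3 and 3 between the 2 drugs compared, the mean r over 20 splits was 0.145 (−0.0249 to 0.330), 0.104 (−0.0395 to 0.256), 0.122 (0.00784 to 0.242), 0.0615 (−0.0888 to 0.223), 0.0339 (−0.132 to 0.229) and −0.052 (−0.194 to 0.142) in that order. RMC-7977 and RMC-4550 shared 1 gene higher, CD36, and 2 lower calls. Independent lists would share 0.00901 and 0.00895, which leaves out the shared Vehicle tumours, and simulated groups shared none but had 0.125 and 0.025 calls on average, too few to set beside these. Of the 79 genes lower under RMC-7977, 89.9%, 84.8% and 94.9% had negative log2 fold changes under RMC-4550, trametinib and cobimetinib. Of the 53 higher ones 92.5%, 73.6% and 52.8% had positive ones, all against the same Vehicle tumours. As many genes of smallest p in the simulations gave 43.4% to 100%, and all but the last share, with a range of 54.7% to 98.1%, lay within their own range. With the Vehicle tumours split, the genes called in each split had the same sign in the other drug at 83.59% (44% to 100%), 79.93% (50.61% to 100%) and 74.65% (40.31% to 94.87%) on average over 20 splits.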

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

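The tests of GC content and of single libraries as a source of the patterns below were chosen only after the results were seen. Among 118 sets of 4 to 6 tumours, 19 values lay far from the rest of their group, where chance picks about 1 in 20 groups, or 6. The share of detected genes with only 1 or 2 counts was 5.0162% in RMC-7977 replicate 3 (18.461% to 18.672% in the rest of its group) and 1.9934% in Trametinib replicate 4 (19.134% to 19.938%). Ribosomal protein genes took 6.9277% of the counts in Vehicle replicate 1 (3.366% to 4.0999%) and 24.985% in Trametinib replicate 4 (3.9334% to 6.5953%). The rank correlation with GC content was −0.6239 in Vehicle replicate 1 (0.3416 to 0.5469). The median correlation with the other tumours was 0.933 in Vehicle replicate 1 (0.9655 to 0.974), 0.9357 in RMC-4550 replicate 1 (0.9704 to 0.9744) and 0.7514 in Trametinib replicate 4 (0.9574 to 0.9735). The MAPK output score was 2.0798 in Trametinib replicate 4 (3.4743 to 3.7111).

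Single genes also stood apart, in CPM. PHLDA1 was at 1.615 in RMC-7977 replicate 3 (1.239 to 1.267 in the rest of its group) and 4.425 in Cobimetinib replicate 1 (2.006 to 2.245), and ETV5 at 3.735 in RMC-7977 replicate 4 (1.109 to 1.445). EPHA4 was at 0.457 in Vehicle replicate 1 and 0.08602 in RMC-4550 replicate 1 (0 in the others), and 3.52 in Trametinib replicate 4 (0 to 0.07533). NRAS was at 169.5 in Vehicle replicate 1 (57.95 to 80.95) and 180.8 in RMC-4550 replicate 1 (90.06 to 91.48). MAP2K2 was at 132.9 in RMC-7977 replicate 3 (182.4 to 187.6) and PPIA at 5978 in Trametinib replicate 4 (1501 to 2104).

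Trametinib against Vehicle gave 3327 genes at an unadjusted p under 0.05 where chance gives 883, but no gene past the threshold. Without Trametinib replicate 4 there were 1287 (899 expected), below the bound of 1.5 times chance set for that library as the cause, but without it and the other 3 libraries apart there were 5772 (888 expected), with 1877 of the 3273 first genes tested there among them (1073 if independent). The GC correction gave 3734 in place of the 3327 and 3660 in place of the 5772, which argues against a GC trend as the whole cause, though the second count fell. With the replicate number as a block there were 369, or 432 with the GC correction, but 3 Vehicle tumours share no number with a drug. Trametinib replicate 4 as the source, since the 5772 are mostly other genes, something shared by tumours of a number, an effect of trametinib, a GC trend as part of the cause and the lower spread of the tumours that remained stay open.

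Cholesterol synthesis genes leaned higher under RMC-7977 than under Vehicle, with a median log2 fold change of 0.4208. It was 0.4064 after the GC correction and 0.3085 without the 2 libraries with few low counts, which argues against these as the whole cause. The mean log2 CPM of the list did not separate the groups (exact permutation p = 0.1143, 3 of 4 tumours above all Vehicle tumours), so the spread between Vehicle tumours stays open, as does an effect of the drug.

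Markers of endothelium, skeletal muscle and blood cells leaned higher in trametinib tumours, with a median of 0.5966 over 12 tested genes, and at −0.1166 without Trametinib replicate 4. In that library CLDN5 was at 88.6 CPM (highest other tumour 167), PECAM1 at 56.8 (48.4), MB at 104 (131), TTN at 19.5 (69.7) and PF4 at 7.68 (0.914). The pattern may therefore come from that library alone, host reads counted as human stay open, and no biological explanation was tested.

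Counts of genes were set beside those of other splits of the same tumours, each fitted with the 2 groups alone. Of 100 splits against Vehicle, 2 gave as many genes as RMC-7977 (91, highest other 916) and 2 as many as RMC-4550 (1, highest other 1729), a share below 0.05. The highest in each put Vehicle replicate 1 with 3 tumours of the drug, and calls many times the real count point to a structure of the samples. With a real count of 0 every split gives as many, which tells nothing: all 100 for trametinib (highest other 0) and cobimetinib (8). Of 35 splits, only the real 1 reached the count for RMC-7977 against RMC-4550 (28, highest other 0) and cobimetinib (265, 1). So it was for RMC-4550 against cobimetinib (22, 0). The real count was again 0, reached by all 35, for RMC-7977 (highest other 368) and RMC-4550 (224) against trametinib and trametinib against cobimetinib (0). The 72 calls of the first come from the fit of all groups. The splits with 368 and 224 again sorted tumours by GC correlation.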

How the results depend on the processing

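Tests without libraries apart, with a GC correction, library weights or only 3 Vehicle tumours were chosen after seeing the data. In this paragraph 10 counts are in the order of RMC-7977, RMC-4550, trametinib and cobimetinib against Vehicle, RMC-7977 against RMC-4550, trametinib and cobimetinib, RMC-4550 against trametinib and cobimetinib, and trametinib against cobimetinib. As reported they were 132, 5, 0, 0, 16, 72, 49, 0, 5 and 0. DESeq2 gave 599, 34, 393, 1, 236, 859, 323, 191, 138 and 114, and shared 131, 5, 16, 61, 49 and 5 of the reported calls where there were any. RLE gave 10 for RMC-4550 against cobimetinib. Library size alone gave 3, 1, 47 and 1 for RMC-4550 and trametinib against Vehicle and for RMC-7977 and RMC-4550 against trametinib. No filter gave 80, 3 and 1 for the first 3, 16 and 25 for RMC-7977 against trametinib and cobimetinib and 3 for RMC-4550 against cobimetinib. A mean CPM of at least 1 gave 301 for trametinib against Vehicle and 14 for RMC-4550 against cobimetinib. Only the 2 groups gave 1 for RMC-4550 against Vehicle, 28, 0 and 265 for RMC-7977 against the other drugs and 22 for RMC-4550 against cobimetinib. With 1 surrogate variable 771, 13, 179, 45, 454, 11 and 153 passed in the comparisons that moved, all but those of trametinib and cobimetinib with Vehicle and with each other. A test against a log2 fold change of 0.5 gave 35, 1, 5, 0, 14 and 0 where the reported count was not 0. The other counts under these settings were within 1.5 times the reported ones, and the cause was not tested.

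Without Trametinib replicate 4 the 10 counts were 541, 11, 1, 2, 105, 28, 202, 0, 90 and 0, without the 2 libraries with few low counts 369, 13, 1, 0, 133, 42, 200, 0, 100 and 0, and without the 4 libraries apart 1134, 11, 2686, 8, 192, 941, 674, 64, 160 and 537. With the GC correction as well, trametinib against Vehicle gave 616, and the other comparisons were not run in that way. The GC correction alone gave 287, 47, 194, 96, 2 and 16 for RMC-7977 against Vehicle and each drug and for RMC-4550 against trametinib and cobimetinib. Library weights gave 2943, 113, 7874, 401, 937, 5291, 1535, 3733, 619 and 6600, but gave Trametinib replicate 2 a weight of 8.82 against 0.85, 0.794 and 0.0529 for the others, so the trametinib values rest almost on 1 tumour. With them VWF in RMC-7977 against trametinib reversed, to 1.65. Against Vehicle replicates 1 to 3 alone RMC-7977 and RMC-4550 gave 17 and 0, and against replicates 5 to 7 alone the 4 drugs gave 373, 2, 43 and 2. Leaving out each tumour gave 43 to 541, 0 to 11, 0 to 1428, 0 to 2, 8 to 105, 0 to 1288, 14 to 202, 0 to 41, 0 to 90 and 0 to 313.

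Over all groups 16 of 36 pairs of tumours with the same number had a correlation over 0.1 and 8 of 22 libraries correlated best with their own number. With the number as a block 2, 0, 0, 31 and 0 genes passed for RMC-7977 and RMC-4550 against Vehicle, RMC-7977 against trametinib and cobimetinib, and RMC-4550 against cobimetinib. With the GC correction in the same fit 2 and 0 passed for RMC-4550 and trametinib against Vehicle. For these 2 the block alone changed no other call than those given with them. The block gave score differences of −2.00, −1.27, −0.93 and −0.35 from Vehicle and −1.52, −0.87 and −0.95 from cobimetinib, none past the threshold, which so few shared numbers cannot reach.

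The score kept its direction in all 7 called differences under every alternative run. Without the 2 libraries with few low counts they were −2.05, −1.50, −1.20 and −0.63 from Vehicle and −1.43, −0.87 and −0.57 from cobimetinib, and without the 4 libraries apart −2.14, −1.41, −1.29, −0.72, −1.43, −0.69 and −0.57. None of these passed, since fewer tumours raise the smallest p of some pairs and so the adjusted p of all. Cobimetinib against Vehicle also lost its call with RLE (−0.62) and without CCND1 and PHLDA1 (−0.52). Leaving out 1 tumour gave −0.72 to −0.52 for it, and −1.64 to −1.43, −1.02 to −0.69 and −1.11 to −0.57 for RMC-7977, RMC-4550 and trametinib against cobimetinib. Correlations of log2 fold changes, for RMC-7977 with RMC-4550, trametinib and cobimetinib, RMC-4550 with trametinib and cobimetinib, and trametinib with cobimetinib, were 0.838, 0.697, 0.684, 0.709, 0.611 and 0.672 over the 134 called genes, chosen against the same Vehicle tumours (the 134 genes of smallest p in simulated unchanged groups gave at most 0.683, 0.627, 0.673, 0.678, 0.664 and 0.673), and 0.145, 0.0615, 0.104, 0.122, −0.052 and 0.0339 with Vehicle split.

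Of 63 calls of named genes 9 held in every alternative, and 398 of 1515 values lost the call, 48 of the 63 under the block, 38 under the test against 0.5, 22 with only the 2 groups and 17 without a filter. Of the calls a setting could change, 25 of 34 were lost against Vehicle replicates 1 to 3 alone and 33, 32, 17 and 27 of 56 without RMC-7977 replicates 1 to 4. Of 287 named values that were not called 113 stayed so throughout. Of 64 camera calls 5 held throughout. Lost were 59 with an estimated correlation, 15 without the 4 libraries apart, 11 with ranks and 7 with GC correction. Simulated changes of 2-fold or less were mostly missed.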

Other observations

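The list tests were planned, but which of them to give here, and the test of GC content, were chosen only after the results were seen. Camera made 27 further calls, in none of which a gene of the list passed over all genes, and each list lost its call with an estimated correlation (adjusted p of 0.129 or more). Autophagy and lysosome genes leaned higher under RMC-7977 than under RMC-4550, trametinib and cobimetinib (22 genes, median log2 fold changes 0.18, 0.34 and 0.16, camera adjusted p = 0.0422, 0.0235 and 0.0364). Ribosome biogenesis genes leaned lower under RMC-7977 than under RMC-4550 and cobimetinib (21 genes, −0.25 and −0.25, camera adjusted p = 0.0166 and 0.00181). Leaving out single tumours was not run for these calls.

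Without Trametinib replicate 4 the first principal component held 32.3% of the variance, and its loadings had a rank correlation of 0.71 with GC content over 10618 genes.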
